A study of Mus musculus with 16 samples.

How the data were processed

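Sections of the aortic valve with adjoining left ventricular myocardium from 16 C57BL/6J mice (8 at P3, 4 females and 4 males at day 30) were assayed on Visium slides as 16 µm fresh frozen sections. Per the submitters' processing notes the reads were processed with Space Ranger against mm10; no version is stated. The deposited values are UMI counts per gene and spot, raw whole numbers without normalization, with 16 libraries joined in 1 matrix. The notes state neither whether depth was equalised when the libraries were joined nor how the spots were chosen.

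Each library was assigned to a mouse by matching the barcode suffix (1 to 16) with the number that ends each sample title. The same 125 barcodes occur under every suffix. The assignment was checked on sex-linked genes: 3 of 4 adult female libraries had more Xist than Y-linked UMIs and 1 had neither, 4 of 4 adult male libraries had more Y-linked UMIs, and 0 went against their label. No 2 libraries of a group were as alike as duplicate sequencing of 1 library would be (chi-square per degree of freedom 2.13 to 36.2 over 40 pairs). The replicate numbers did not pair adult females with males (correlations of -0.0177, -0.372, 0.194 and -0.0152), so mice were treated as unpaired. The adult valve label follows sex, and valves and replicates are numbered separately at each age, so no label ties mice of both ages together.

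Depth was 21526 to 116126 UMIs per mouse. A count of 0 excludes levels above 3 counts with 95% confidence, which is 25.8 to 139 CPM depending on the mouse. The biological coefficient of variation was 0.29 for age, 0.28 for sex and 0.29 for the parts of the tissue.

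For age and sex, UMIs of all spots were summed per mouse, genes were filtered with filterByExpr, scaled with TMM and tested by edgeR 4.0.16 quasi-likelihood F tests, two-sided, with Benjamini-Hochberg adjustment at 0.05. Levels are given in CPM (UMIs of a gene scaled to the library total), and scaled CPM use TMM factors. Scaling by library totals, an alternative below, used the summed UMIs of the tested genes in each library, without TMM factors. Log2 fold changes by age are the mean of the female and male changes in the edgeR model. They need not equal the ratio of mean scaled CPM, which divide by the total over all genes. Gene lists were written before the data were examined, counted over all genes tested and again with adjustment over the list alone, and tested as sets with camera (limma 3.58.1), at its preset correlation and with an estimated correlation. DESeq2 1.42.0 was the second tool, in R 4.3.3. List totals per mouse, Eln per marker UMI and library measures were compared by two-sided exact permutation tests over all 12870 groupings of 8 and 8 mice, adjusted over 33 measures.

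Spots with at least 100 UMIs were normalized to 10000, log-transformed, reduced to 2000 variable genes outside the tested lists, scaled with a limit of 10 and clustered (20 components, 15 neighbours, Leiden resolution 0.5, seed 0) with scanpy 1.11.5 and leidenalg 0.10.2 in Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Genes had to be present in at least 10 spots. A cluster was named by at least 3 markers of a cell type, each with at least 20 UMIs and 1.5-fold over the other spots with an offset of 50 CPM, unless a marker of another type was among its 10 leading genes. Regional levels are summed UMIs with exact Poisson intervals, which cover counting error only; the rule of size asks for 1.5-fold (2-fold as the alternative) and 20 UMIs, and list medians were set against 10000 random lists matched on expression. Regions were tested in edgeR with mouse as block in mice with at least 1000 UMIs in both. In a further comparison the spots of each mouse were ranked by their share of myocardium-marker UMIs and divided into 3 equal parts, and the low-myocardium and high-myocardium parts were compared in edgeR with mouse as block. Correlations with Eln used genes in at least 5% of spots (10% as the alternative) and a mean over at least 8 mice. Pigment spots had at least 1 UMI of the core pigment list, and shares with an Eln UMI were taken after 1 random thinning of each spot to 100 UMIs, drawn anew for each set of spots, and as the average over all thinnings.

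The rule for naming genes was set before the data were examined. In the age and sex tests it takes, in each direction, the 15 genes with the lowest adjusted p among those under 0.05 with an absolute log2 fold change of at least 1, and list members that passed. In the region and pigment comparisons it takes elastic fibre and pigment genes with at least 20 UMIs and the 4 members of any other list with the most UMIs, and for correlations the 20 highest and 5 lowest genes. Some genes that the rule names are not reported here, and the counts of results in the closing part leave them out. Named outside it, after their values were seen, were genes that did not pass the main test over all genes (Ltbp4, Fbln1, Vim, Actc1, Fabp4 and Smtn by age, and Eln, Col3a1, Acta2, Myl4, Myl7, Nppa and Sln by sex), pigment genes under 20 UMIs, genes given by UMI totals, and Mgp and Apoe in the comparison of parts. Gene positions are those of GENCODE M21 (GRCm38, the assembly of mm10), matched by gene ID for 286 of 286 genes.

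Several choices were made after the data were seen. A first naming of clusters at 2-fold left no myocardium region and was replaced by 1.5-fold. A first version of the naming left out the rule on leading genes, which was then applied, and the earlier naming is kept as an alternative. The minimum of 1000 UMIs per region, the comparison of parts, the tests of list totals and of Eln per marker UMI, the ratios of Eln within each age, by region and for pigment spots, and within mice, these also with each mouse left out, the average over all thinnings, and the alternatives of library totals, of subsets of spots, libraries or genes, and of a myocardium covariate were added too. Alternatives set before were other UMI minimums (none, 300), Leiden resolution 1.0, 1000 variable genes, all genes in the clustering, means over spots, DESeq2, no filter, a replicate block and leaving out each mouse.

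The tests were run on simulated data with 2-fold and 4-fold changes over 5 simulations. The age test recovered 76% and 90.4% of changed genes with 3.59% of calls on unchanged genes, and the sex test 53.6% and 84.8% with 3.62%. The test of parts recovered 98.1% and 100% of the changed genes that entered it, but these were 20.4% and 20% of all changed genes, and 12.6% of its calls were unchanged genes, above the nominal 5%. Tissue images and spot positions were not analysed here.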

Results

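Spatial transcriptomes were recorded from sections through the aortic valve and the adjoining left ventricular myocardium of 16 C57BL/6J mice. The mice were 8 pups at postnatal day 3 (P3), 4 adult females and 4 adult males at day 30. Each mouse gave 1 library of 125 spots, a spot being a barcoded patch of the slide that captures RNA from the several cells above it. The libraries held 979593 unique molecular identifiers (UMIs, each counting 1 captured transcript) over 2000 spots, and 14864 of 55487 genes had at least 1 UMI. The P3 mice 1 to 8 had 116126, 42406, 30045, 85488, 74302, 22115, 50420 and 48805 UMIs. Adult females 9 to 12 had 91561, 88996, 62423 and 45146 UMIs, and adult males 13 to 16 had 81365, 68806, 50063 and 21526 UMIs. The mean total was 58713 ± 31283 (SD, n = 8) at P3 and 63736 ± 24097 (SD, n = 8) in adults, and the median number of UMIs per spot was 254 ± 194 (SD, n = 8) and 144 ± 122 (SD, n = 8). At these totals a count of 0 allows up to 25.8 to 139 CPM (UMIs of a gene scaled to the library total), depending on the mouse. Mitochondrial genes held 9.32% ± 1.99 (SD, n = 8) of UMIs at P3 and 21.6% ± 6.27 (SD, n = 8) in adults, a difference with p = 0.000155 in a two-sided exact permutation test, the smallest value 8 against 8 mice can give (adjusted p = 0.000733 over 33 measures).

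The first comparison, P3 against adult mice, asks how elastic fibre transcripts differ with age in sections of the valve and adjoining myocardium. Spot positions were not analysed, so no difference can be placed in the valve itself. Eln, which encodes tropoelastin, the soluble precursor of elastin (ENSMUSG00000029675, GRCm38 chromosome 5, 134702593 to 134747323), fell from 6816 ± 4541 (SD, n = 8) scaled CPM at P3 to 656 ± 990 (SD, n = 8) in adults, with a log2 fold change of -4.07 (SE 0.54, adjusted p = 1.65e-06). The log2 fold changes by age average the female and male changes in the edgeR model, so they differ from the ratio of such means. Lox, the lysyl oxidase that starts the cross-linking of elastin and collagen (ENSMUSG00000024529, chromosome 18, 52516067 to 52529867), fell by 3.97 on the log2 scale (SE 0.55, adjusted p = 3.15e-06). Mfap2, a glycoprotein of the microfibrils on which elastin is laid down (ENSMUSG00000060572, chromosome 4, 141010418 to 141015984), fell by 3.71 (SE 0.48, adjusted p = 1.05e-06). Without adult female 10 it fell by 4.40. Of 12 elastic fibre genes tested, 10 fell and 0 rose, and 10 fell adjusted over the list alone. Fbln5 and Emilin1, both needed to organise elastic fibres, had log2 fold changes of -2.27 and -2.01. Fbn1, the main microfibril protein (ENSMUSG00000027204, chromosome 2, 125300594 to 125507993), Fbln2 and Loxl1 had -1.64, -1.72 and -1.64. Mfap4 (-1.15) and Ltbp3 (-0.77) also passed, while Ltbp4 (-0.25, SE 0.22, adjusted p = 0.349) and Fbln1 (0.03, SE 0.37, adjusted p = 0.949) did not. Under scaling by library totals, here the UMIs of the tested genes in each library without TMM factors, 11 of the 12 fell, Ltbp4 being the addition. As a set the list passed as lower than the other genes tested only with a preset correlation (camera, adjusted p = 0.000479). With the correlation of 0.484 estimated between its genes it did not pass (camera, adjusted p = 0.426). The calls for Mfap4 and Ltbp3 were lost when single mice were left out, Mfap4 without P3 mouse 1 (-0.87, adjusted p = 0.069) and Ltbp3 without any 1 of 7 mice.

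Elastin transcripts were also compared with those of the cells that make matrix. The fibroblast and valve interstitial markers held 16209 ± 6112 (SD, n = 8) CPM at P3 and 5679 ± 4328 (SD, n = 8) in adults (two-sided exact permutation p = 0.00233, adjusted p = 0.00592). Per 100 of these marker UMIs, P3 mice had 45.9 ± 22.1 (SD, n = 8) Eln UMIs and adults 8.71 ± 5.82 (SD, n = 8), a 5.27-fold difference with 8 of 8 adults below the lowest P3 mouse (two-sided exact permutation p = 0.000155, the smallest possible, adjusted p = 0.000733). Measured against single markers, the fold was 22.7 per Dcn UMI, 7.05 per Vim UMI and 4.45 per Col1a2 UMI. The other elastic fibre genes together had 28.4 ± 3.16 (SD, n = 8) UMIs per 100 marker UMIs at P3 and 33.2 ± 7.33 (SD, n = 8) in adults (two-sided exact permutation p = 0.12, adjusted p = 0.188). Eln alone held 8199 ± 5592 (SD, n = 8) unscaled CPM at P3 and 563 ± 870 (SD, n = 8) in adults (two-sided exact permutation p = 0.000466, adjusted p = 0.0014), with 7 of 8 adults below the lowest P3 mouse. The exception, adult male 16, carried the adult mean, which was 259 ± 131 (SD, n = 7) without it, and the log2 fold change of -4.07 was then -4.69.

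**Figure D1:**
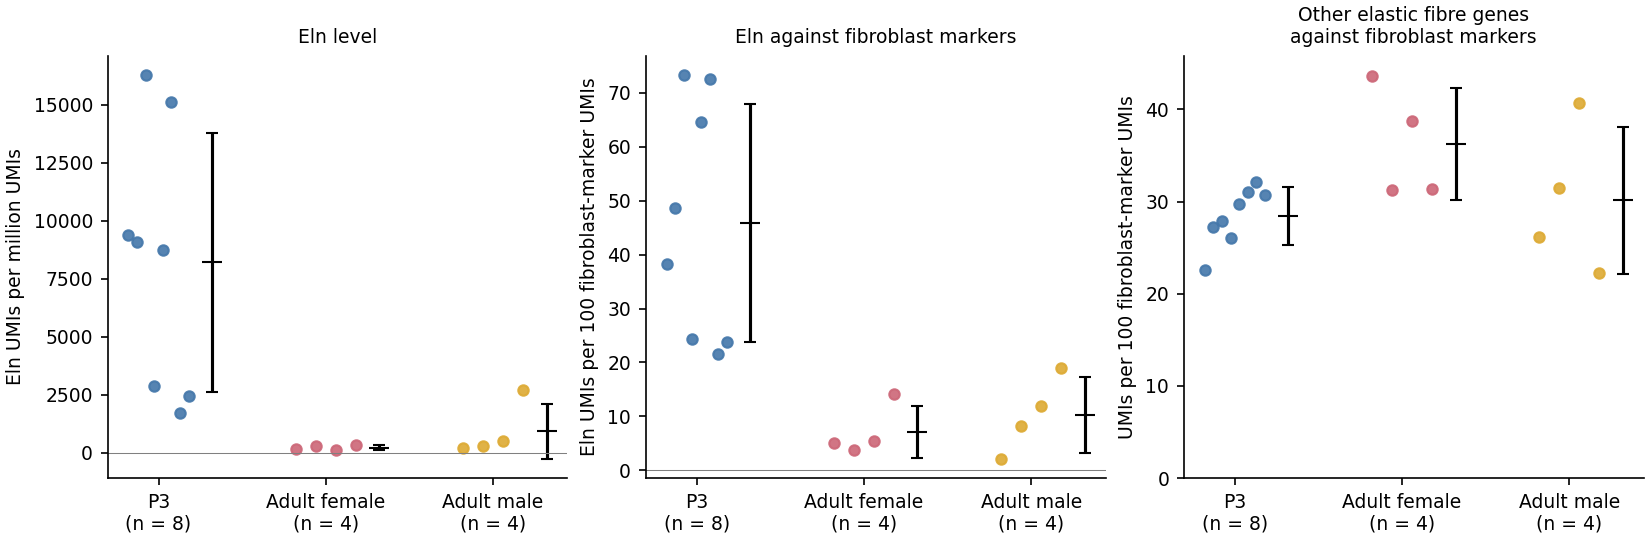
Eln CPM (left), Eln UMIs per 100 fibroblast-marker UMIs (middle) and UMIs of the other elastic fibre genes per 100 fibroblast-marker UMIs (right) in each mouse (points), with mean ± SD (bars) for P3 (n = 8), adult females (n = 4) and adult males (n = 4). All 8 adults lie below the lowest P3 mouse in the middle panel, where the means are 45.9 at P3 and 8.71 in adults.

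Collagens and fibroblast markers were tested beside the elastic fibre genes. Of 9 collagen genes tested outside the marker lists, 8 fell and 0 rose (8 adjusted over the list alone), led by Col5a1 (-2.38, SE 0.28, adjusted p = 3.09e-07) and Col5a2 (-2.14, SE 0.33, adjusted p = 1.16e-05), which nucleate collagen fibrils, and by Col6a3 (-1.43). The list's set test had adjusted p = 0.00687 with a preset correlation and adjusted p = 0.426 with an estimated correlation. Of 9 fibroblast and valve interstitial markers, 5 fell and 1 rose, also adjusted over the list alone. Postn, a matricellular protein of developing valves, had -3.08 (SE 0.31, adjusted p = 3.03e-08), Col3a1 -2.61, Col1a1 -2.39, Col1a2 -1.76 and Sparc -1.08. Dcn, the collagen-binding proteoglycan decorin, rose by 0.89 (SE 0.28, adjusted p = 0.0123), but not under library totals, where 6 markers fell with Vim added, nor without adult female 10 (0.60, adjusted p = 0.056). The marker list's set test had adjusted p = 0.00687 with a preset correlation and adjusted p = 0.503 with an estimated correlation. Aspn, a small proteoglycan that binds collagen, fell by 2.64, as 1 of 2 proteoglycan genes tested.

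Of 16 myocardium markers, 8 rose and 1 fell (8 and 1 adjusted over the list alone): the oxygen store Mb by 1.93 (SE 0.20, adjusted p = 7.35e-08), the calcium pump Atp2a2 by 1.22, Tnni3 by 1.26, Ttn by 1.08 and Tpm1 by 0.97, while Myl3, Tnnc1 and Pln rose by less. Under library totals 5 markers rose and 2 fell, with Actc1 added to Myh7, and Myl3, Tnnc1 and Pln were no longer called. The set test had adjusted p = 0.0295 with a preset correlation and adjusted p = 0.624 with an estimated correlation. Among 10 genes of the neonatal-to-adult switch, 3 fell and 2 rose, the same counts adjusted over the list alone. Tnni1, the troponin I of the fetal heart (ENSMUSG00000026418, chromosome 1, 135779434 to 135810989), fell from 1790 ± 400 (SD, n = 8) to 21.5 ± 27.2 (SD, n = 8) scaled CPM, a log2 fold change of -6.82 (SE 0.36, adjusted p = 3.14e-13). The adult level rests on 8 UMIs, and the log2 fold change was -7.88 without adult female 9. H19, an imprinted RNA of fetal growth, fell by 5.04 (SE 0.49), and Myh7, the myosin heavy chain of the fetal mouse ventricle, had -3.54 (SE 0.33). Acta1 rose by 2.13 (SE 0.35) beside Tnni3. This list was lower as a set with adjusted p = 0.0295 at a preset correlation and adjusted p = 0.426 with an estimated correlation, and under library totals 4 members fell and 2 rose.

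**Figure D2:**
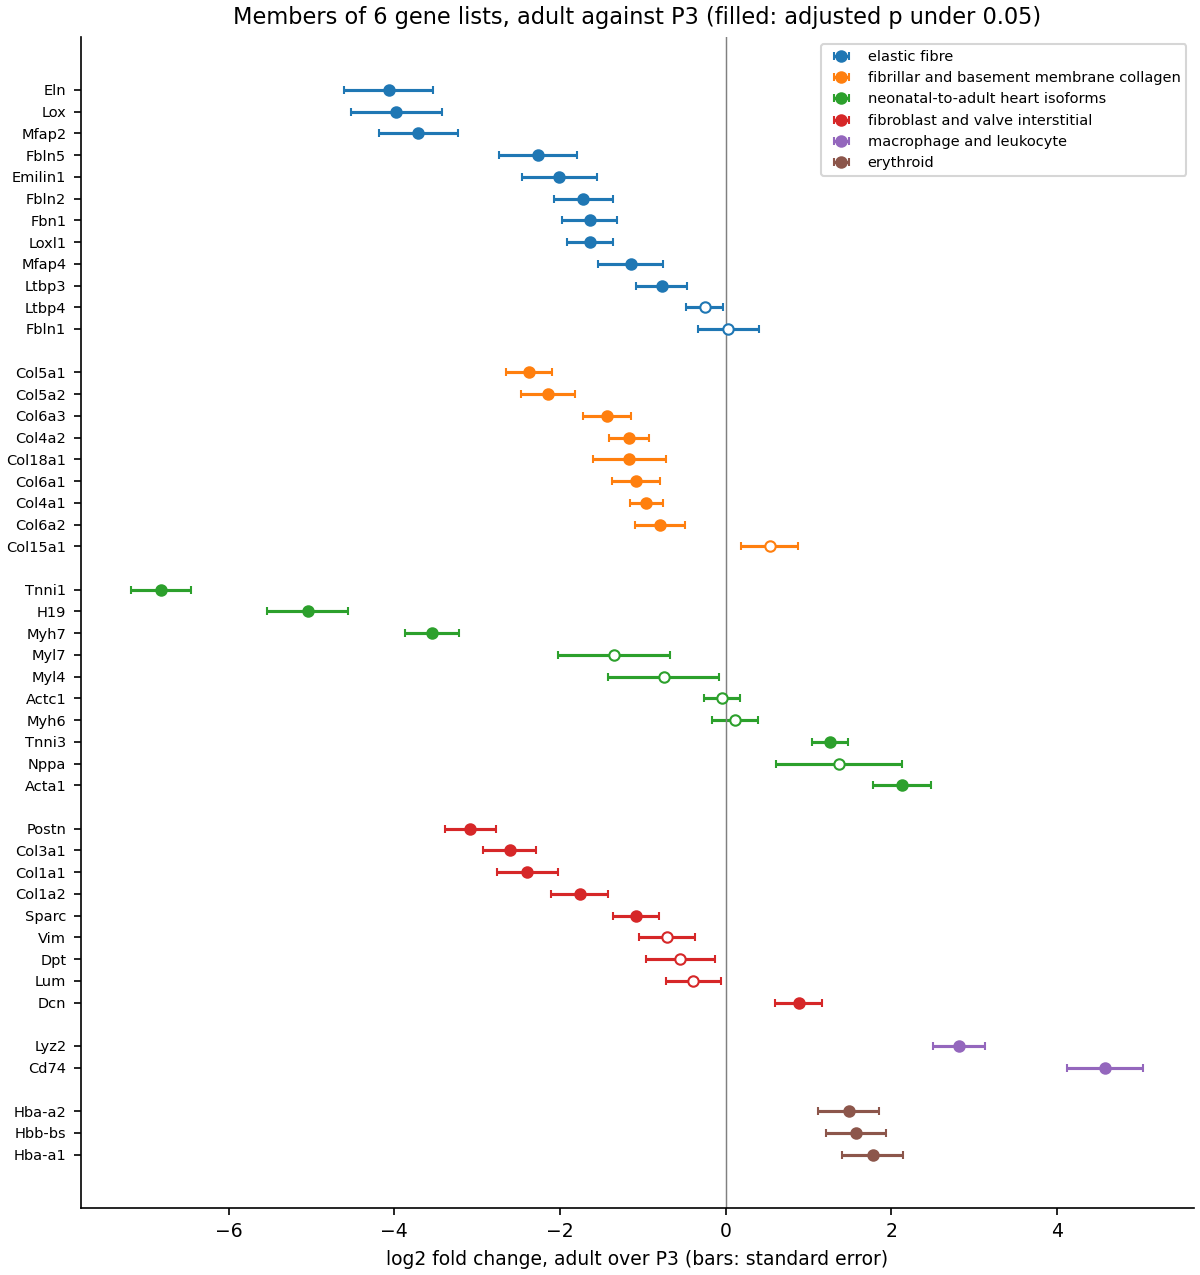
Log2 fold change, adult over P3, ± SE, for the tested members of 6 gene lists (n = 8 mice at each age), with filled points for an adjusted p under 0.05. Eln is at -4.07 and Tnni1 at -6.82. Under library totals of the tested genes the values of all 993 genes tested shift by a median of -0.44. Among the genes plotted, Dcn is then no longer called, and Actc1, Vim and Ltbp4 count as lower.

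Among the other genes that passed, Ckmt2, the mitochondrial creatine kinase of heart muscle (ENSMUSG00000021622, chromosome 13, 91853387 to 91876885), rose from 49.0 ± 54.9 (SD, n = 8) to 1949 ± 599 (SD, n = 8), a log2 fold change of 5.01 (SE 0.34, adjusted p = 7.05e-11). Oxct1, which lets the heart burn ketone bodies, rose by 3.14, Lpl, which frees fatty acids from lipoproteins, by 2.08, and Cox7a1, a muscle subunit of cytochrome oxidase, by 2.31. Rpl3l (4.19), Tcap (2.57), Hrc (2.37), Eef1a2 (2.18), S100a1 (1.90), Ifi27l2a (4.20) and Gsn (2.48) also rose. Both macrophage and leukocyte markers tested rose (2 of 2 adjusted over the list alone), Cd74, the invariant chain of class II antigen presentation (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), by 4.58 (SE 0.46, adjusted p = 3.38e-08) and Lyz2 by 2.81 (SE 0.31). Among the genes that fell were the imprinted Mest (-5.81, or -6.55 without adult female 11), the Wnt modulator Sfrp2 (-4.65, or -5.49 without adult male 13), the potassium channel subunit Kcne1 (-3.30) and Nrep (-3.04). The tubulins Tubb5 (-2.46) and Tuba1b (-1.87), the actin-binding Tmsb10 (-2.14) and the prolyl isomerase Ppia (-1.61) fell as well. All 3 erythroid markers tested rose (Hba-a1 1.78, Hbb-bs 1.58, Hba-a2 1.49; set test adjusted p = 0.0679 with a preset and adjusted p = 0.503 with an estimated correlation).

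Vessel markers were mixed. Of 5 endothelial markers, Aqp1 rose by 1.12 while Egfl7 (-1.07) and Cldn5 (-0.93) fell, and under library totals Fabp4 joined the genes that fell. Of 5 smooth muscle markers, Acta2 fell by 1.73 (2.40 without adult male 16) and Rgs5, a pericyte gene, had 0.58 (adjusted p = 0.0474), which did not pass adjusted over the list alone, nor under library totals, where Smtn fell too. Id3, 1 of 2 TGF-beta and BMP genes tested, fell by 0.94, and Mmp2, 1 of 3 proteases and inhibitors tested, fell by 0.71. The calls of Cldn5, Mmp2, Rgs5, Col18a1, Col6a2 and Tnnc1 were each lost without any 1 of several mice. The 4 atrial markers tested did not pass, and no member of the pigment cell, Notch, cell cycle, mast cell, adipocyte, Schwann, mesothelial, airway, thymus or valve endothelial lists had enough UMIs for the test.

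Over all 993 genes tested, 500 differed between the ages (edgeR quasi-likelihood, two-sided, adjusted p under 0.05), 234 of them higher and 266 lower in adults. With the replicate number of the labels as a block 405 genes passed, 388 of them shared with the 500. Scaling by library totals of the tested genes in place of TMM moved the median log2 fold change by -0.44. It gave 96 genes higher and 434 lower, so that 46.8% or 18.1% of called genes rose, depending on the scaling. Totals over all genes were not tried. The share of mitochondrial UMIs rose with age, as did 8 of 16 myocardium markers, while 1 fell. The fold changes of other genes therefore include any change in the share of tissue under the spots. With the myocardium-marker level of each mouse as a covariate, 315 genes passed and 6 elastic fibre genes fell, the calls of Fbn1 (adjusted p = 0.0829), Fbln2 (adjusted p = 0.0554), Mfap4 and Ltbp3 being lost. The labels number valves and replicates separately at each age and tie no mice of both ages together, so batch and age cannot be told apart, and the block joins equal numbers only.

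Lists too sparse for gene tests were compared as CPM per mouse, a comparison chosen after the data were seen. Cell cycle genes held 528 ± 201 (SD, n = 8) at P3 and 92.0 ± 87.5 (SD, n = 8) in adults (two-sided exact permutation p = 0.000311, adjusted p = 0.00128), with Mki67 at 25 UMIs over all P3 mice and 3 over all adults. Mast cell genes held 240 ± 127 (SD, n = 8) and 33.4 ± 54.9 (SD, n = 8; 18.3 ± 37.1, n = 7, without adult male 16) (exact permutation p = 0.000932, adjusted p = 0.00256), among them the proteases Cma1 with 55 and 7 UMIs and Tpsb2 with 27 and 1. Mesothelial and epicardial genes held 197 ± 262 (SD, n = 8; 107 ± 56.1, n = 7, without P3 mouse 3) and 11.5 ± 12.8 (SD, n = 8), with 8 of 8 adults below the lowest P3 mouse (exact permutation p = 0.000155, adjusted p = 0.000733). Macrophage and leukocyte genes went from 301 ± 105 (SD, n = 8) to 930 ± 390 (SD, n = 8), with 8 of 8 adults above the highest P3 mouse (exact permutation p = 0.000155, adjusted p = 0.000733), and the complement genes C1qa and C1qb from 15 to 49 and from 20 to 50 UMIs. Notch pathway genes held 435 ± 127 (SD, n = 8) and 237 ± 117 (SD, n = 8) (exact permutation p = 0.0087, adjusted p = 0.0191), a call lost without mitochondrial and haemoglobin genes (adjusted p = 0.0503). The pigment cell core list held 29.8 ± 28.0 (SD, n = 8) and 49.8 ± 112 (SD, n = 8) (exact permutation p = 0.89, adjusted p = 0.947), and without adult male 13 the adult mean lay below that of P3, at 11.2 ± 29.7 (SD, n = 7).

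**Figure D3:**
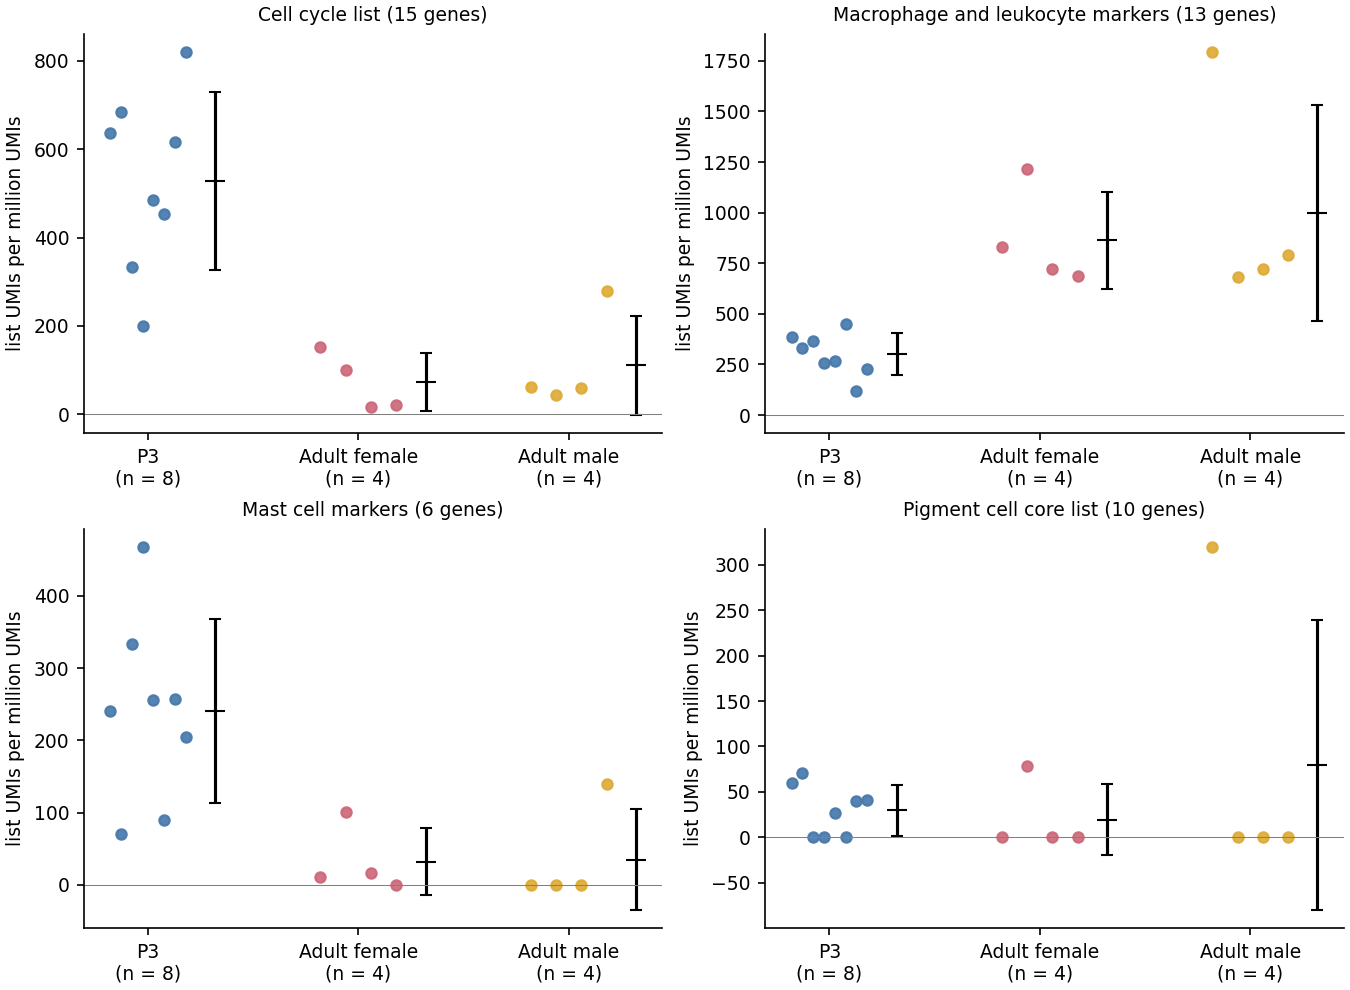
CPM of the cell cycle, macrophage and leukocyte, mast cell and pigment cell core lists in each mouse (points), with mean ± SD (bars) for P3 (n = 8), adult females (n = 4) and adult males (n = 4). The means went from 528 to 92.0 for the cell cycle list and from 301 to 930 for the macrophage list between P3 and adult mice.

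The second comparison, adult females against adult males, asks whether the sexes differ in the same sections at day 30. Eln had 210 ± 109 (SD, n = 4) scaled CPM in females and 944 ± 1241 (SD, n = 4) in males, a log2 fold change of 2.03 (SE 0.80, adjusted p = 0.719). None of 723 genes tested passed (edgeR, two-sided), 47 had an unadjusted p under 0.05, DESeq2 also called 0 with 36 under 0.05, and a replicate block called 0. Adjusted over the list alone, Col3a1 (1.74, SE 0.50) among 8 fibroblast markers and Acta2 (2.75, SE 0.87) among 2 smooth muscle markers were higher in males. As sets, fibroblast markers (adjusted p = 3.2e-07) and 4 elastic fibre genes (adjusted p = 0.0019) were higher in males with a preset correlation, and both had adjusted p = 0.305 with an estimated correlation. Without the filter on low counts 11 genes were higher in males, for 6 of which adult male 13 held the most male UMIs (98.0% to 98.8% for the atrial genes Myl4, Myl7, Nppa and Sln) and for 5 adult male 16 (36.9% to 70%). Eln rested on adult male 16: the ratio of male to female CPM without TMM factors was 4.36, and 1.54 without that mouse. Adjusted over the list alone, no fibroblast marker passed without adult female 9, 11 or 12, and no smooth muscle marker without these or adult male 16. The set tests were not repeated without single mice. The valve label of the adults coincides with sex, so those cannot be told apart.

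The third comparison asks which part of the tissue carries elastin transcripts. Clustering of 1338 spots with at least 100 UMIs, made without the tested gene lists, gave 4 groups, of which 2 could be named. A matrix region of 683 spots, named by 7 fibroblast and valve interstitial markers, was led by Eln, Sfrp2, Mfap2, Lox and Col1a1, and a myocardium region of 179 spots, named by 5 myocardium markers, was led by Ckmt2, Rpl3l, Cox7a1, Tcap and Mb. A group of 320 spots led by Lars2, Gm42418 and mitochondrial genes had too few markers for a name. Another of 156 spots with 7 fibroblast markers stayed unnamed, since Myh7 was among its 10 leading genes beside H19 and Tnni1. The regions followed age: 653 of the 683 matrix spots came from P3 mice and 169 of the 179 myocardium spots from adults. Eln had 10926 CPM in the matrix region (95% exact Poisson interval 10495 to 11371) and 266 (217 to 324) in the myocardium region, a ratio of 41.0 (33.6 to 50.6) that holds the age difference as well. Within P3 spots the ratio was 3.13 (2.42 to 4.12) over 10 myocardium spots, 8 of them from P3 mouse 1. Without that mouse it was 4.07 (1.12 to 33.6) over 2 myocardium spots. Within adult spots the ratio was 7.52 (2.61 to 17.8) over 30 matrix spots with 6 Eln UMIs, 4 of them from adult male 16. Without adult male 16 it was 2.95 (0.346 to 11.4). These intervals cover counting error only. Of 8 mice with spots in both regions, 3 had more Eln per UMI in the matrix region. This count decides nothing: 4 of the other 5 had 0 Eln UMIs among only 244 to 1097 matrix UMIs and P3 mice 7 and 8 had 1 myocardium spot each.

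The gene lists were compared between the regions as well, and their folds hold the age difference too, as those of the fetal genes Tnni1 (1845 and 76.5 CPM) and H19 (1018 and 36.9) show. By a rule of size without a test (1.5-fold and at least 20 UMIs), 17 of 19 elastic fibre genes were higher in the matrix region, with Fbln5 at 529 and 36.9 CPM, Lox at 289 and 13.2, and Mfap2 at 380 and 15.8. The list's median fold of 3.15 exceeded all of 10000 lists matched on expression (percentile 100), beside percentiles of 99.99 for collagens, 99.97 for proteoglycans and 99.91 for TGF-beta and BMP genes. Among the members of the other lists that met the UMI minimum, 1.5-fold differences were found in 11 of 12 for collagens, 4 of 7 for proteoglycans, 5 of 7 for TGF-beta and BMP, 2 of 3 for Notch, 4 of 7 for proteases and 2 of 2 for the cell cycle, and 6 of 12 isoform genes were higher and 3 lower. A paired edgeR test over the 3 mice with at least 1000 UMIs in both regions (P3 mouse 1, adult males 13 and 15) called 23 of 323 genes, 20 of them higher in the matrix region. Among them were the elastic fibre genes Eln (2.45, SE 0.77, adjusted p = 0.0293, higher in 2 of 3 mice) and Fbln2 (1.55, SE 0.53, adjusted p = 0.0498), both also adjusted over the list alone, and Bgn (2.55), Timp2 (2.76) and Timp3 (2.74). The atrial marker Sln was called too (1.49, SE 0.48, adjusted p = 0.0366, higher in 2 of 3 mice), and all 4 atrial markers were higher adjusted over the list alone, adult male 13 being the adult male with 24716 CPM of atrial markers where the next had 363. Both elastic fibre calls were lost without any 1 of the 3 mice, and the total fell to 9 genes without P3 mouse 1, 1 without adult male 13 and 0 without adult male 15.

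A comparison within each mouse, chosen after the regions proved to follow age, used the spots of each mouse ranked by their share of myocardium-marker UMIs. Eln was higher in the part with the fewest myocardium UMIs than in the part with the most, by 1.88 on the log2 scale (SE 0.33, adjusted p = 0.00012) and in 15 of 16 mice. At P3 the means were 13592 ± 9397 (SD, n = 8) and 4826 ± 3803 (SD, n = 8) scaled CPM, and in adults 1121 ± 1362 (SD, n = 8) and 214 ± 288 (SD, n = 8). Adult male 16 had the highest adult value in both parts, 4079 and 900, and raised both adult means. The count of 15 mice holds weak cases, since adult parts had only 0 to 26 Eln UMIs each. Adult female 11 had 1 UMI in the low-myocardium part and 2 in the other (118 and 110 scaled CPM). P3 mouse 8 had 2285 and 2054 scaled CPM. The exception, adult female 9, had 0 and 2 UMIs. Bgn, a small proteoglycan of valve matrix, was higher by 2.02 (SE 0.32, adjusted p = 8.25e-05), and Mgp, an inhibitor of calcification, by 1.60. All 6 fibroblast markers tested were higher, Vim by 1.87, Col1a1 by 1.75, Col1a2 by 1.69, Col3a1 by 1.47, Sparc by 1.43 and Postn by 1.41 (6 adjusted over the list alone; set test adjusted p = 2.15e-05 with a preset and adjusted p = 0.0539 with an estimated correlation). Acta2 was higher by 1.02 and Apoe by 1.31. Over all, 85 of 177 genes passed (edgeR with mouse as block, two-sided), 55 higher and 30 lower in the low-myocardium part. Since the parts were set by myocardium counts in the same spots, myocardium genes are lower and other genes higher there partly by construction, and in simulated data 12.6% of the calls were unchanged genes (0 calls where no gene was changed). The calls of Acta2 and Postn were lost in P3 mice alone, and without the filter on low counts also those of Col1a1, Col3a1 and Sparc. Whether the difference of 1.88 for Eln depends on age was left open by the interaction test (0.77, SE 0.68, adjusted p = 0.997), in which edgeR called 0 of 177 genes and 6 had an unadjusted p under 0.05. Adjusted over the list alone, the difference between parts was larger in adults for 3 of 6 fibroblast markers, Postn (2.54, SE 0.63), Vim (1.82, SE 0.52) and Col3a1 (1.25, SE 0.47), and for the 1 smooth muscle marker, Acta2 (1.74, SE 0.55).

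**Figure D4:**
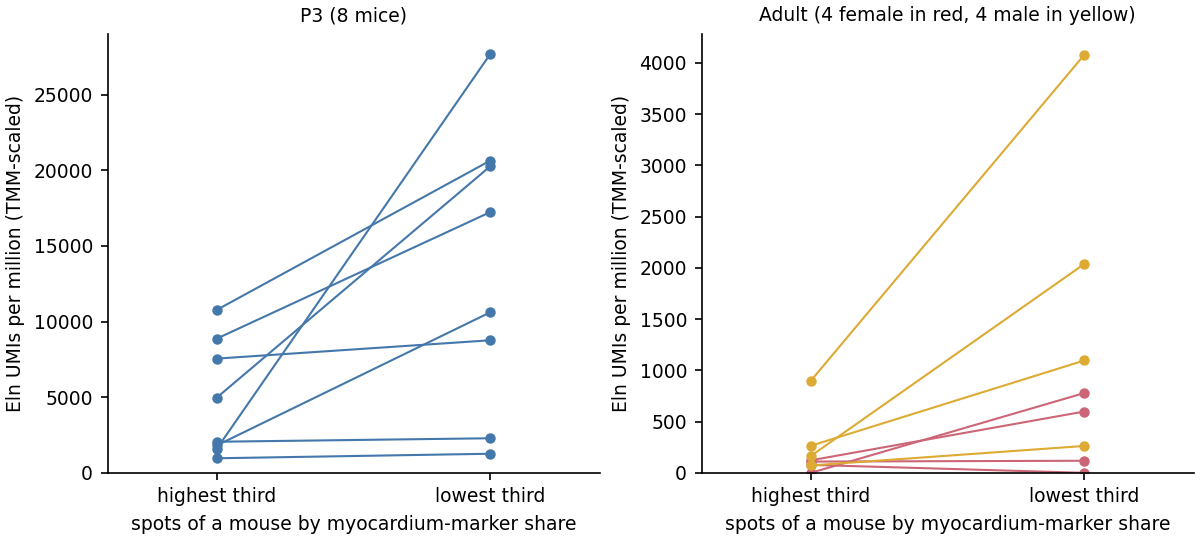
Eln in scaled CPM in the parts of each mouse with the highest and the lowest share of myocardium-marker UMIs, joined by 1 line per mouse, for P3 (n = 8) and adult mice (n = 8). Eln was higher in the low-myocardium part in 15 of 16 mice, though adult parts held only 0 to 26 Eln UMIs each.

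A further question is which genes share spots with Eln. Spearman correlations were taken across the spots of each mouse and averaged over mice; spots are not independent replicates, so no p was computed. Among 1645 genes the highest mean was that of the mesenchymal filament gene Vim (0.178 ± 0.161 SD, n = 16 mice, positive in 15), followed by Mgp (0.152), Sparc (0.149), Ece1 (0.145), Col1a2 (0.138) and the elastin-associated Ltbp4 (0.131). Mice counted equally, though Eln held a mean of 8199 CPM at P3 and 563 in adults. The means at P3 and in adults were 0.122 and 0.233 for Vim, 0.128 and 0.176 for Mgp, and 0.147 and 0.151 for Sparc. They were 0.0496 and 0.240 for Ece1, 0.130 and 0.146 for Col1a2, and 0.0659 and 0.197 for Ltbp4. This ranking depends on the processing: of the 20 highest genes, 1 was shared after regression on log depth, 6 with a 300-UMI minimum, 10 without a minimum, 12 among genes in at least 10% of spots, 14 with Pearson correlation and 13 without adult female 9 or 12. The lowest were mt-Cytb (-0.164), mt-Nd4 (-0.147), Myl2 (-0.135), mt-Nd2 (-0.133) and Tnnc1 (-0.121). The 13 elastic fibre genes measured all had positive means, with a median of 0.060 above 99.95% of matched random lists. Other matrix lists lay near it, with medians of 0.067 for 3 TGF-beta and BMP genes (percentile 97.4), 0.065 for 3 proteases and inhibitors (95.1), 0.052 for 4 proteoglycans (96.1) and 0.043 for 10 collagens (98.0). Fibroblast markers had a median of 0.092 (percentile 100) and myocardium markers -0.065 (percentile 1.6). Endothelial and smooth muscle markers had medians of 0.027 (percentile 68.3) and 0.031 (percentile 64.3).

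The last comparison concerns melanocytes, which the series title names as contributors to elastogenesis. Transcripts of 10 core pigment cell genes were rare, with 49 UMIs in 29 spots of 7 mice, 16 of them at P3 and 33 in adults. Dct, a melanin synthesis enzyme (ENSMUSG00000022129, chromosome 14, 118012790 to 118052244), had 16 UMIs, the melanosome genes Pmel and Mlana 13 each and Tyrp1 4, while Slc45a2, Oca2 and Gpr143 had 0. Adult male 13 held 26 of the 49 UMIs in 8 spots, and 12 of them lay in 1 spot. Mitf and Ednrb, which other cells also express, had 26 and 19 UMIs. In the 28 pigment spots with at least 100 UMIs, Eln had 3340 CPM (95% exact Poisson interval 2740 to 4033) and in the 1310 other spots 3626 (3503 to 3751). The ratio of 0.921 (0.753 to 1.12) pools both ages, so it holds the age difference as well. Within P3 spots the ratio was 1.18 (0.956 to 1.44). With 1 P3 mouse left out it ran from 0.935 (0.598 to 1.396, without P3 mouse 1) to 1.29 (1.04 to 1.58, without P3 mouse 3). Within adult spots the ratio was 1.80 (0.843 to 3.42), or 1.10 (0.295 to 2.91) without adult female 10 and 2.74 (0.985 to 6.15) without adult male 13. Measured against the other spots of the same mouse, pigment spots held 108 Eln UMIs where 90.4 were expected, a ratio of 1.19 (0.98 to 1.44), above the expected number in 7 of 7 mice. This within-mouse ratio, chosen after the data were seen, was 1.13 (0.919 to 1.38) over 5 P3 mice and 2.59 (1.24 to 4.76) over adult female 10 and adult male 13, the latter on 10 Eln UMIs where 3.86 were expected. Without P3 mouse 1, which held 74 of the 108 UMIs, the ratio of 1.19 became 1.81 (1.26 to 2.53), and that of 1.13 became 1.61 (1.03 to 2.40). The adult ratio was 1.82 (0.497 to 4.67) without adult female 10 and 3.59 (1.32 to 7.82) without adult male 13. The difference between the ages was not tested, and the intervals treat UMIs as independent and cover neither the spread between mice nor the number of ratios computed. Within the matrix region 9 pigment spots gave a ratio of 1.28 (0.989 to 1.63). In the spots of neither named region 17 pigment spots gave 0.753 (0.534 to 1.03). In the myocardium region 2 pigment spots gave 0.497 (0.0125 to 2.83). These 3 ratios also pool both ages. At an equal depth of 100 UMIs per spot, 1 random thinning left an Eln UMI in 25% of pigment spots (Clopper-Pearson interval 10.7 to 44.9) and 32.7% of other spots (30.1 to 35.3). The average over all thinnings was 24.8% and 31.7%. Within each age, 1 thinning gave 50% (23.0 to 77.0) and 51.0% (47.4 to 54.5) at P3, and 14.3% (1.78 to 42.8) and 5.21% (3.49 to 7.45) in adults. The averages were 44.1% and 49.8% at P3, and 5.53% and 5.55% in adults. No order of pigment and other spots is read from these shares. The ratio of 0.921 became 0.483 without P3 mouse 1 and 1.38 without adult male 13.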

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

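All explanations in this part were tested after the results were seen. In groups of 4 or 8 mice, a mouse was singled out when its gap to the next one exceeded Dixon's 95% critical value. This held in 32 of 210 groups (15.2%) over 71 measures. Adult male 16 had 9, adult male 13 had 6, adult female 10 had 5, adult females 11 and 12 and P3 mice 2 and 3 had 2 each, and adult female 9 and P3 mice 4, 7 and 8 had 1 each. Many measures overlap, so these are not independent.

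Adult male 16, the adult with the fewest UMIs, stood apart in genes of matrix and contractile cells, values given with the next mouse of its group. Eln had 2694 CPM (next 499), or 3076 scaled (578), Fbln5 583 (92.6), Mfap4 371 (208) and Col3a1 2652 (909). Vascular smooth muscle markers had 7712 (1758), Schwann and neuronal markers 232 (86.0), mast cell markers 139 (0) and cell cycle genes 279 (61.5). Gm42418 and Lars2 held 6.62% of the UMIs of this mouse, against 2.80% in the next adult male. No biological explanation was tested, and the cause was not tested.

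Adult male 13 had 24716 CPM of atrial myocardium markers (next 363), 430.2 of the pigment cell list (43.6), 320 of its core (0), 1794 of macrophage and leukocyte markers (790), and scaled levels of 429.9 for Lyz2 (265) and 12.3 for Sfrp2 (0). Adult female 10 had 78.7 of the pigment core (0), 2697 of proteoglycan and cartilage-type genes (732), 303 of Notch genes (155), 101 of mast cell markers (16.0), and a scaled level of 194 for Tubb5 (63.3). The cause was not tested for either mouse.

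Among the other adults, female 12 had 14.1 Eln UMIs per 100 fibroblast-marker UMIs (next 5.41) and the lowest Tcap at 1165 (2169). Female 11 had 16.0 of airway markers (0) and 19.9 for Mest (0), and female 9 had 25.3 for Tnni1 (0). At P3, mouse 3 had 832 of mesothelial and epicardial markers (211) and 860.4 for Fbln5 (438), mouse 2 had 47.2 of thymus markers (0) and 1351 for Tmsb10 (946), mouse 4 had 11.7 of airway markers (0), mouse 7 had 176 for Ckmt2 (58.5) and mouse 8 had 1097 for Cox7a1 (615). Values beside a next mouse at 0 rest on few UMIs.

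The lower Eln of the adults could follow from the mix of tissue under the spots. Fewer matrix-producing cells as the whole cause is argued against by Eln per 100 fibroblast-marker UMIs, which was 5.27-fold higher at P3 (two-sided exact permutation p = 0.000155, the smallest possible, 8 of 8 adults below the lowest P3 mouse). More myocardium as the whole cause is argued against by a log2 fold change of -2.87 with the myocardium-marker level as covariate (edgeR, adjusted p = 2.5e-05), against -4.07 without it. Without mitochondrial and haemoglobin genes the log2 fold change was -4.09 (edgeR, adjusted p = 1.51e-06). This is no test of a larger mitochondrial share as the cause. Mean shares of 9.32% at P3 and 21.6% in adults are too small for their removal to bring -4.07 near 0. A biological difference of age and a batch per age stay open, since no label ties mice of both ages together. Other tissue under the spots, such as smooth muscle, was not tested as a cause and stays open too. Adult male 16, the adult with the most Eln, also stood apart in smooth muscle markers, at 7712 CPM (next adult male 1758).

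For the other elastic fibre genes, fewer matrix-producing cells in adult spots stays open as a possible explanation. Their UMIs per 100 fibroblast-marker UMIs were 1.17-fold higher in adults (two-sided exact permutation p = 0.12), which does not show that they did not differ. Such a ratio cannot tell fewer cells from fewer matrix transcripts per cell, since 5 of 9 markers tested fell themselves and 1 rose. It also pools genes that fell, such as Lox and Mfap2, with Ltbp4 and Fbln1, which did not pass.

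Other splits of the mice were tried for each test of many genes. For age, 1 of 100 splits, the real one, gave as many genes (500, the highest other 0), so chance can be excluded at 0.05. For the low-myocardium and high-myocardium parts 1 of 100 did (85, the highest other 1), which decides nothing, since the parts were set by counts of genes in the test. With the replicate number as a block in edgeR, 405 genes differed by age (388 shared with the 500) and 0 by sex (36 at an unadjusted p under 0.05). For sex, 35 of 35 splits gave as many genes as the real split (0, the highest other 9), which decides nothing, since any split reaches 0. For regions, 1 of 4 splits gave as many (23, the highest other 0), which are too few splits for a share under 0.05.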

How the results depend on the processing

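The scaling by library totals, the subsets of spots, libraries and genes, the covariate, each age alone, and the naming without the rule on leading genes were chosen after the data were seen. Over 176 results and 3481 alternatives, 3186 kept their direction and side of the threshold, or stayed within their spread or a fixed fold. A further 144 fell short of the threshold, 13 newly passed it, 137 moved further than their spread or the fixed fold, and 1 reversed. The fixed fold was used for counts of genes, which have no measured spread. List counts by age made up 89 of the 137. In all, 107 results were the same throughout. Of 1679 alternatives for single genes by age, 1560 were the same and 118 fell short.

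By age, 500 genes became 863 without the filter, of which only 338 were shared with the 500. They became 49 in the low-myocardium part (215 tested), 174 in the high-myocardium part (410 tested) and 315 with the myocardium covariate. With 1 mouse left out they ran from 399 to 582. The 10 elastic fibre genes became 3 and 2 in these parts and 6 with the covariate, and 7 to 10 with 1 mouse left out. Pln reversed, from 0.48 to -0.064, in the high-myocardium part; the cause was not tested. By sex, 0 genes became 11 without the filter (0 to 0 with 1 mouse left out). Between the parts, 85 genes became 35 in P3 mice and 42 in adults, with fewer mice each (67 to 90 with 1 left out), and the interaction went from 0 to 1 gene under library totals (Postn, 2.62, SE 0.61, adjusted p = 0.035).

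By region, 23 genes became 10 with a 300-UMI minimum and 71 without the rule on leading genes. Leaving out 1 of the 3 mice gave 9 (P3 mouse 1), 1 (adult male 13) and 0 (adult male 15). The 2 elastic fibre genes became 1 and 1, and 0 to 0 with 1 mouse left out. The Eln ratio of 41.0 became 10.98 with a 300-UMI minimum, 102 at Leiden 1.0, 9.48 with 1000 variable genes, 11.7 with all genes, 24.9 without the rule on leading genes and 24.2 as a mean over spots, and ran from 34.2 (without adult female 9) to 74.0 (without P3 mouse 1). At Leiden 1.0 the rule of size gave 11 elastic fibre genes against 17, and 20 members of the other lists against 34. The matrix region then held 42179 UMIs against 221121, so fewer genes may have reached the minimum of 20 UMIs. No region value exists without a UMI minimum, without mitochondrial and haemoglobin genes or with naming at 2-fold, which leave no pair of named regions, and Leiden 1.0 gave no region test for want of mice.

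For pigment spots the Eln ratio of 0.921 became 0.717 as a mean over spots, 0.436 with at least 2 UMIs and 0.621 without Pmel. With 1 mouse left out it ran from 0.483 (without P3 mouse 1) to 1.38 (without adult male 13). These ratios pool both ages and hold the age difference as well. Of the 32332 UMIs of pigment spots in the main setting, 20654 were from adults. In the matrix region 1.28 became 0.955 at Leiden 1.0, 0.853 with 1000 variable genes, 0.839 with all genes and 0.645 without the rule on leading genes. Without thinning, 71.4% of pigment spots and 52.3% of other spots had an Eln UMI, against 25% and 32.7% in 1 random thinning and 24.8% and 31.7% averaged over all thinnings. The higher share of the deeper pigment spots (medians of 806.5 and 301 UMIs) was thus not seen at equal depth. The average for pigment spots ran from 17.9% (without P3 mouse 1) to 32.5% (without adult male 13). The cause of the other changes was not tested. The median correlation of elastic fibre genes with Eln ran from 0.047 to 0.101 over 22 alternatives; its spread over mice is larger than the median. The pigment results rest on 49 UMIs, 26 of them from adult male 13.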

Other observations

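The values in this part were chosen after the data were seen and were not tested gene by gene. UMI counts of single genes are pooled over the mice of each age, so they do not show how many mice carry them. Some matrix genes had more UMIs in the adults, in a total of similar size. Comp, a cartilage matrix protein, had 6 UMIs over the 8 P3 mice and 65 over the 8 adults, Chad 2 and 24, Prg4, the lubricant of joint surfaces, 7 and 38, and Cytl1 8 and 45. Acan, the large proteoglycan of cartilage, went the other way with 26 and 2, and Fmod had 45 and 44. As a list, proteoglycan and cartilage-type genes held 2099 ± 908 (SD, n = 8) CPM at P3 and 1451 ± 1021 (SD, n = 8) in adults (two-sided exact permutation p = 0.198, adjusted p = 0.284). The adults were uneven: female 10 had 2697 CPM of this list and the next female 732, while the males ran from 959 to 2927.

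Fbn2, the fibrillin of early microfibrils, had 53 UMIs at P3 and 1 in adults. The mesothelial genes Upk3b and Msln had 22 and 1, and 25 and 0. Cfd, a complement factor of fat cells, was listed at 0 at P3 and had 61 UMIs in adults, where the adipocyte list held 345 ± 405 (SD, n = 8; 215 ± 184, n = 7, without adult male 16) CPM against 92.1 ± 44.2 (SD, n = 8) (two-sided exact permutation p = 0.0295, adjusted p = 0.0534).

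Other list totals in CPM, P3 then adult (SD, n = 8, two-sided exact permutation tests), were as follows. Elastic fibre genes held 12708 ± 7052 and 2231 ± 1622 (adjusted p = 0.0014) and collagens 3639 ± 911 and 1436 ± 723 (adjusted p = 0.0014). Myocardium markers held 72741 ± 17325 and 95735 ± 17111 (adjusted p = 0.0383), a call lost on leaving out any 1 of 10 mice (P3 mice 1, 2, 3 and 6, adult females 9 to 12, adult males 14 and 15; adjusted p up to 0.076). Erythroid markers held 1048 ± 652 and 2457 ± 1299 (adjusted p = 0.033), also lost without P3 mouse 1, 3 or 4, adult female 12 or adult male 14 or 15 (adjusted p up to 0.0644), and endothelial markers 2497 ± 483 and 1870 ± 251 (adjusted p = 0.0191; 0.177 without mitochondrial and haemoglobin genes). Proteases and inhibitors (1365 and 888, adjusted p = 0.0534), TGF-beta and BMP genes (1256 and 823, adjusted p = 0.188), isoform genes (30027 and 26995, adjusted p = 0.584) and valve endothelial markers (142 and 105, adjusted p = 0.459) did not pass. Nor did Schwann markers (126 and 85.4, adjusted p = 0.279), atrial markers (4859 and 3899, adjusted p = 0.944), smooth muscle markers (2558 and 1780, adjusted p = 0.584) or the full pigment list (77.7 and 103, adjusted p = 0.91). Without adult male 16 the adjusted p was 0.0055 for TGF-beta and BMP genes, 0.0246 for Schwann markers and 0.0022 for smooth muscle markers (adult mean 933). Without adult male 13 it was 0.0263 for atrial markers (adult mean 925). The full pigment list turned without adult male 13, with an adult mean of 56.4, below that of P3 (adjusted p = 0.474). Proteases and inhibitors passed without P3 mouse 4 (adjusted p = 0.0495), P3 mouse 7 (0.037), adult female 10 (0.0391), adult male 13 (0.0376) or adult male 16 (0.0288), and adipocyte markers without P3 mouse 5 (0.0496) or adult female 11 (0.0087), in spots with at least 100 UMIs (0.0476) and without mitochondrial and haemoglobin genes (0.0147). Airway (1.46 and 2.00) and thymus markers (5.90 and 4.77) held 2 and 4 UMIs in all.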
